A study of Glycine max with 6 samples.

How the data were processed

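Chromatin of formaldehyde-fixed embryos was sonicated to 100 to 500 bp and either kept as input or incubated with 2 ug of antibody, and libraries were amplified with 15 PCR cycles, per the labels' protocols. The 6 libraries comprised 2 with Ab1, 2 with Ab2 and 2 of input, and groups and replicate numbers were taken from the sample titles. Bowtie 0.12.7 and MACS2 are named in the submitters' processing notes, which give no version for MACS2. The genome build is not given in the sources used here.

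Each immunoprecipitated library had its own peak list in the narrowPeak format, with 1 summit per interval, and lists were compared as separate replicates. The peak names of Ab1 replicate 2 alone carry the tag "cat", which the labels do not explain, so whether that list was made from several sequencing runs is not known; this bears on its recovered depth. The fold enrichment over background, a ratio at the summit, was computed by the authors' peak caller and used as deposited. The −log10 p and −log10 q of each peak were likewise taken from the deposited lists, in which every peak had a q-value of at most 0.01. The integer score of each peak was deposited by the authors and entered no result. Fold enrichment described, ranked or filtered peaks within their list, was averaged over the replicates of an antibody to describe single regions, and with the p gave the recovered values below. Its ranks over shared regions were also compared between libraries, and its size was not tested between them.

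Regions were built by merging intervals of the 4 lists that shared at least 1 base, and a region counted as found in a library when a peak of that library lay in it. Peaks with a −log10 q of at least 2 were used, which removed none. Peaks on scaffolds, 0.484 to 0.550% of each list, were kept except in positions along chromosomes and in chance overlaps. Chance overlap was estimated by shifting one list circularly along each of the 20 chromosomes by a random distance, in 1000 draws, and again with shifts of 10 to 100 kb. The observed overlap in those tests was counted on the chromosomes with the compared lists alone, and so differs slightly from the counts of regions over all 4 lists. Shares are given with 95% Wilson intervals, and a share of 0 with the limit that 3 counts of the total allow. The ratio of peaks between antibodies was tested by an exact permutation of the 4 log2 counts.

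Read totals were not used here. The number of fragments and the background at each summit were recovered from the deposited fold enrichment and −log10 p, taking the fold as fragments plus 1 over background plus 1 and the p as the upper Poisson tail, as MACS2 computes them. The recovered fragments were whole numbers within 0.01 for 100% of peaks in 3 libraries. In Ab1 replicate 2 they were whole for 2.08% of peaks as deposited and for 100% after the pile-up was divided by a scale of 0.881, which is the inverse of its depth relative to the input. The median number of fragments at the summit was 26 and 35 in Ab1 replicates 1 and 2, and 19 and 18 in Ab2 replicates 1 and 2. Depth relative to the input was 0.654, 1.13, 0.493 and 0.537 in the same order. Relative depths across libraries also rest on the shortest peak being the fragment length, and the input depths recovered from the different lists came to 2.03 times that of Ab2 replicate 1.

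The replicate numbers pair the libraries across antibodies. The design text describes biological replicates that each have both antibodies and an input. Over shared regions with summits at most 5 bp apart, backgrounds over 10 kb were the same within 1 input fragment in 85.2% and 83.9% of cases between libraries of the same number, and in 4.67% and 4.01% between libraries of different number. Rank deviations of fold enrichment over the 15473 shared regions correlated at r = 0.355 between libraries of the same number; this is across regions, which are not independent replicates.

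The alternatives were a −log10 q of at least 5, lists of equal length (21291 peaks by p), summits within 150 bp, a reciprocal overlap of at least 50%, an irreproducible discovery rate of at most 0.01 by a copula mixture, and each library left out in turn. Summits within 150 bp were joined in chains, so the outer summits of a region could lie further apart. With the reciprocal overlap, shared regions were counted as peaks of Ab1 replicate 1, and Ab2 regions and their share found with Ab1 as peaks of Ab2 replicate 1. The irreproducible discovery rate was run on lists already restricted to low q-values. On simulated data, the fragments of 99.98% of peaks were recovered, and 92.5% of true pairs passed the irreproducible discovery rate with a false share of 1.00%. The simulated pairs stood further from noise than the fits to these lists and were not filtered by q. Those rates therefore do not carry over to the real lists. Unrelated lists placed evenly along the chromosomes overlapped at 1.01 times chance, which does not test clustered lists such as these. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

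Before the data were examined, named genes were to be the studied gene, the 10 genes whose promoters held the strongest shared regions by mean rank of fold enrichment, up to 3 genes of each preset gene list, and the 5 strongest regions of each antibody alone by the smaller fold of the replicates. No genome or annotation of the build of the lists was used here. The planned analyses of promoters, gene lists, motifs and antigen matches were therefore not run, the gene of GLYMA.04G093300 was not placed, and the rule was applied to regions in place of genes. A gene table of the assembly Glycine_max_v4.0 was not used to place peaks, since peaks ran past its last genes on several chromosomes. Coordinates are 1-based.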

Results

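The binding of the soybean protein GLYMA.04G093300 to chromatin was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in embryos of the cultivar Williams 82. Embryos at early maturation, the phase in which a seed begins to fill with reserves, were dissected from seeds of 6 to 7 mm. Antibodies raised against 2 peptides of the protein, given in the labels as residues 117 to 132 and 170 to 180 (the sequence given for the latter is 1 residue shorter than its range), were each used on 2 biological replicates, and 2 libraries of total chromatin served as input. The antibodies are called Ab1 (anti-peptide 1) and Ab2 (anti-peptide 2) here; that their numbers follow the order in which the labels list the peptides is implied and not stated. Peak lists of the 4 immunoprecipitated libraries were analysed, and no peak list of the input libraries was used here. Coordinates are those of the deposited lists, whose genome build is not given in the sources used here.

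Both Ab1 libraries held more peaks than both Ab2 libraries. Ab1 gave 59261 peaks in replicate 1 and 44181 in replicate 2, a mean of 51721 ± 10663 (SD, n = 2). Ab2 gave 28010 and 21291 peaks, a mean of 24650.5 ± 4751 (SD, n = 2). Ab1 peaks were also longer, with median lengths of 358 and 309 bp against 257 and 226 bp, and covered 25.5 and 16.3 Mb against 8.42 and 5.64 Mb. The median fold enrichment given by the authors was 4.69 and 4.31 in the Ab1 lists and 5.10 and 5.16 in the Ab2 lists. These medians cover different sets of peaks and do not rank the antibodies. Over the regions with a peak in all 4 libraries the order was the opposite, with medians of 7.59 and 5.96 for Ab1 and 5.92 and 5.51 for Ab2. The ratio of Ab1 to Ab2 peaks was 2.10 (two-sided exact permutation test of log2 counts, p = 0.333, the smallest p that 2 libraries against 2 allow). The sequencing depth in reads is unknown, and the relative depths recovered from the peak values were 1.33 and 2.30 for Ab1 replicates 1 and 2 and 1.09 for Ab2 replicate 2, with Ab2 replicate 1 set to 1. The longer list of each antibody, that of replicate 1, therefore came from the library of lower recovered depth, at 0.576 times the depth of replicate 2 for Ab1 and 0.918 times for Ab2. The list of Ab1 replicate 2 was the only one whose recovered values needed rescaling, and how its reads were put together is not known.

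The first question was how far the replicates of each antibody marked the same places. Merging the intervals of all lists gave 64222 regions, of which 37561 held a peak in both Ab1 libraries and 15768 in both Ab2 libraries. Of the peaks of Ab1 replicate 2, 89.9% lay in a region that also held a peak of Ab1 replicate 1, and 64.5% the other way round. For Ab2, 82.0% of the peaks of replicate 2 lay in a region of replicate 1 and 63.0% the other way round. A further 23650 regions, 36.8% of all, held a peak in 1 library only, and 18544 of them were of Ab1 replicate 1.

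On the 20 chromosomes, the lists of the Ab1 replicates overlapped in 37395 regions against 2127 ± 234 (SD over 1000 draws) when one list was shifted along each chromosome. The Ab2 replicates overlapped in 16121 regions against 355 ± 44.9. These were 17.6 and 45.4 times the chance overlap, and no draw was as large (one-sided permutation p = 0.001 for each, the smallest that 1000 draws can give). The ratios do not rank the antibodies, since longer lists of longer peaks overlap more by chance. Shifts of only 10 to 100 kb, which keep the regional density of peaks, gave 9.36 and 23.7 times. The counts depended on how reproducibility was defined: an irreproducible discovery rate of at most 0.01 kept 11696 Ab1 and 2601 Ab2 regions, and lists of equal length gave 16042 Ab1 regions. Without Ab1 replicate 2 the remaining Ab1 list stood for 58568 regions, and without Ab2 replicate 2 the remaining Ab2 list stood for 25883.

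The second question was whether antibodies to separate peptides of the protein recovered the same regions. All 4 libraries held a peak in 15473 regions, 24.1% of all (95% Wilson interval 23.8 to 24.4), with a median length of 602 bp and 10.7 Mb covered. Of the regions found in both Ab2 libraries, 98.1% (97.9 to 98.3) were found in both Ab1 libraries. Of those found in both Ab1 libraries, 41.2% (40.7 to 41.7) were found in both Ab2 libraries and 31.8% (31.4 to 32.3) in neither. With the strongest 21291 peaks of every library, so that all lists had equal length, these shares were 83.8% of the Ab2 regions and 72.8% of the Ab1 regions. At that length, the share of the regions of 2 lists that held a peak of both (Jaccard index) was 0.619 between Ab1 replicates and 0.517 between Ab2 replicates. It was 0.555 to 0.596 between libraries of different antibodies, so the index of the Ab2 replicates was below that of libraries of different antibodies. That length kept every peak of Ab2 replicate 2 but dropped the weaker peaks of the other lists, and Ab1 peaks were longer in the full lists. The lower index alone therefore does not show that the Ab2 replicates were less reproducible. The share of the Ab2 regions depended on the matching as well, at 88.6% (88.1 to 89.1) with summits within 150 bp and 58.3% (57.5 to 59.2) when intervals had to overlap by at least 50% of both lengths. It was 87.6% when the longer Ab2 list, that of replicate 1, stood for Ab2 alone.

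**Figure D1:**
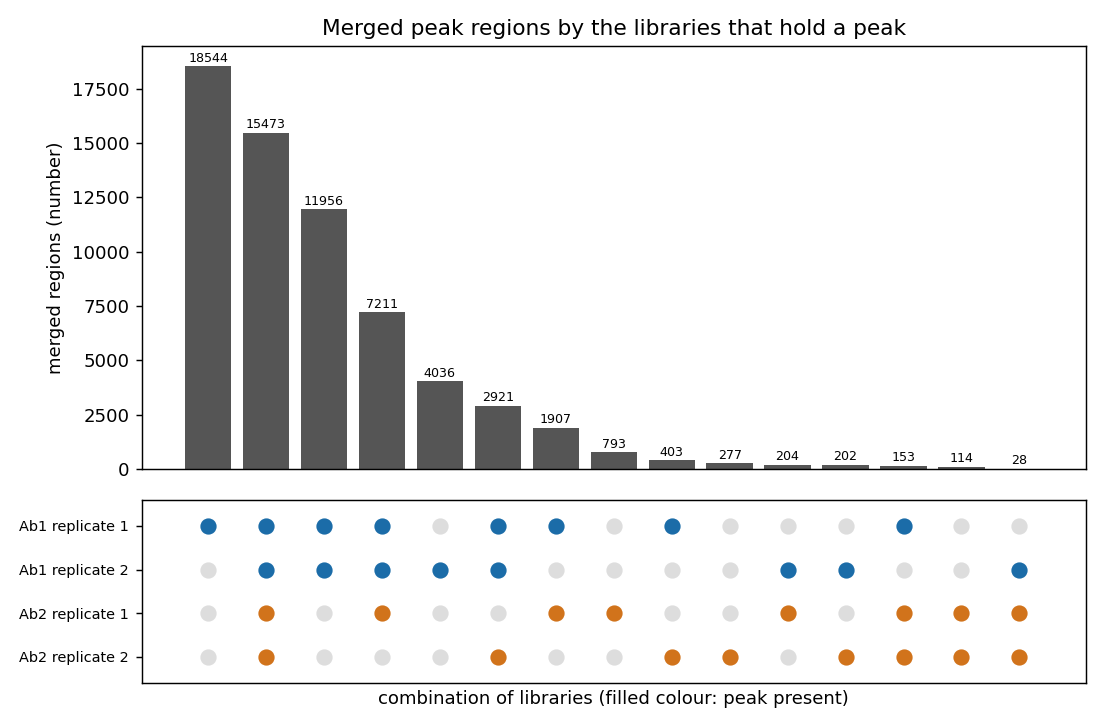
Number of merged regions (vertical axis) for each combination of libraries that held a peak, marked by filled points under the bars, blue for Ab1 and orange for Ab2. Regions of Ab1 replicate 1 alone were the most frequent class with 18544, followed by the 15473 regions of all 4 libraries and the 11956 of both Ab1 libraries alone.

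The regions of the 2 antibodies overlapped in 15151 places on the chromosomes against 596 ± 70.2 by chance, or 25.4 times (one-sided permutation p = 0.001, the smallest that 1000 draws can give), and 13.1 times with shifts of 10 to 100 kb. The shifts test against random placement only. Both antibodies were used on the same replicates, and libraries of the same number appeared to share their input. No control immunoprecipitate was among the libraries, so binding of the protein was not told apart from unspecific precipitation. Within the regions of all 4 libraries, the summits spanned a median of 81 bp (quartiles 51 and 141), and in 61.5% of regions the 4 summits lay within 100 bp. The number of shared regions fell to 5774 when intervals had to overlap by at least 50% of both lengths and to 2567 with the irreproducible discovery rate. The 5774 are peaks of Ab1 replicate 1, and counted as peaks of Ab2 replicate 1 the number was 7813. The Wilson intervals cover counting error only.

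Recovery with Ab2 followed the strength of a region in the Ab1 lists. Among the weakest 10% of the Ab1 regions by fold enrichment, 2.77% (2.29 to 3.34) were found in both Ab2 libraries and 78.2% in neither. Among the strongest 10%, 99.0% (98.6 to 99.3) were found in both and 0 of 3757 in neither, which allows a share of up to 0.0799% (3 counts of the total).

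**Figure D2:**
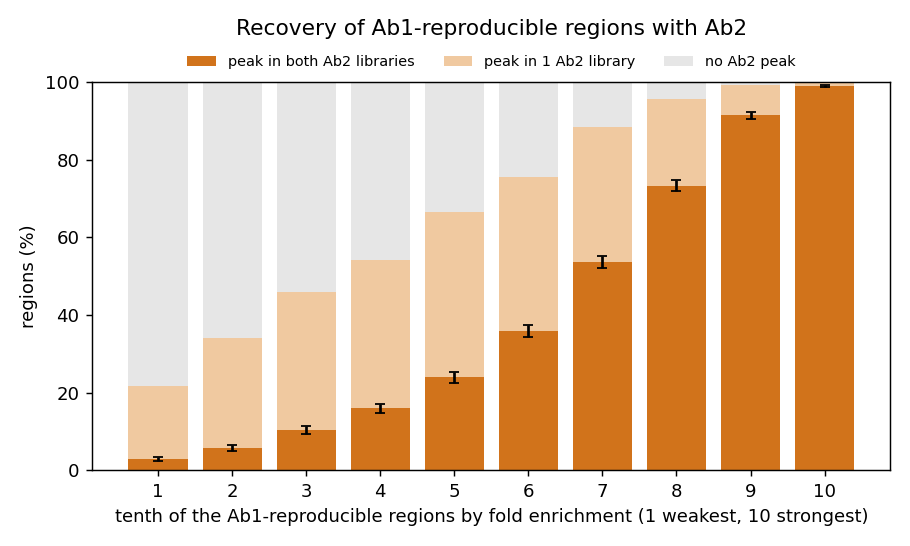
Percentage of the Ab1 regions (vertical axis) that held a peak in both, 1 or neither Ab2 library, in 10 groups of increasing fold enrichment in the Ab1 lists (horizontal axis), with 95% Wilson intervals on the share found in both. The share found in both rose from 2.77% in the weakest group to 99.0% in the strongest.

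The strongest shared regions were picked by mean rank of fold enrichment over the 4 libraries, so that they stand high in every list by choice. The first was on chromosome 11 from 7351004 to 7351618, with a fold enrichment of 22.3 ± 7.23 (SD, n = 2) with Ab1 and 22.2 ± 1.68 (n = 2) with Ab2. The next was on chromosome 8 from 6830607 to 6831228, at 22.6 ± 0.522 with Ab1 and 20.2 ± 0.539 with Ab2. Chromosome 13 from 32211997 to 32212962 followed at 20.2 ± 1.78 and 17.2 ± 0.187. A second region of chromosome 8, from 3852375 to 3854145, reached 18.4 ± 1.60 and 17.7 ± 0.814. The other 6 of the strongest 10 lay on chromosomes 18, 17, 10, 19 and 12, with 2 of them on chromosome 18. The region on chromosome 19 from 4297727 to 4298293 had 16.7 ± 0.689 with Ab1 and 20.8 ± 0.851 with Ab2. Folds were scaled within each library, so their differences between antibodies were not tested.

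**Figure D3:**
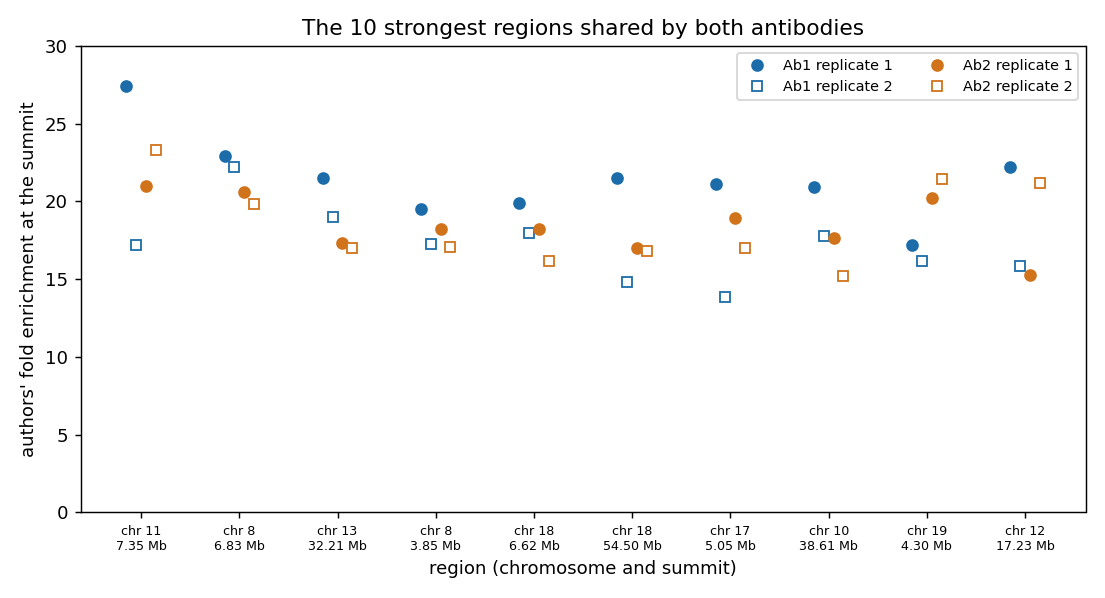
Fold enrichment at the summit as given by the authors (vertical axis) in each of the 4 libraries for the 10 strongest shared regions (horizontal axis), with filled points for replicate 1 and open squares for replicate 2. In the chromosome 11 region the Ab1 replicates stood at 27.4 and 17.2, and the Ab2 replicates at 21.0 and 23.3.

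The longest shared region spanned 3986 bp on chromosome 11, from 3239410 to 3243395, with a fold enrichment of 8.95 ± 1.29 (SD, n = 2) with Ab1 and 7.23 ± 0.129 (n = 2) with Ab2. A region of 3340 bp on chromosome 5, from 37790595 to 37793934, had 6.82 ± 0.501 and 6.30 ± 0.0114. One of 3338 bp on chromosome 13, from 24596765 to 24600102, had 10.0 ± 1.00 and 8.00 ± 0.571. These 3 regions were chosen for their length after the data were seen.

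Regions found with 1 antibody alone had a lower median fold enrichment than the regions of all 4 libraries. Requiring a peak in all 4 libraries itself selects strong regions, so the classes favour this order by their definition. Both Ab1 libraries and neither Ab2 library held a peak in 11956 regions, whose median fold enrichment was 4.36 in Ab1 replicate 1 and 3.79 in Ab1 replicate 2, against 7.59 and 5.96 for the regions of all 4 libraries. The strongest of them, on chromosome 13 from 33279117 to 33279481, had a fold enrichment of 7.23 ± 0.483 (SD, n = 2). Regions on chromosome 8 from 1037203 to 1037784, chromosome 7 from 11984137 to 11984584 and chromosome 15 from 22376511 to 22377129 followed at 7.06 ± 0.275, 7.05 ± 0.426 and 7.04 ± 0.577. The fifth, on chromosome 13 from 38877843 to 38878552, had 6.63 ± 0.0499.

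Both Ab2 libraries and neither Ab1 library held a peak in 114 regions. Their median fold enrichment was 1.66 in replicate 1 and 1.61 in replicate 2, and in 96 of them (84.2%, 76.4 to 89.8) the recovered background was at least 10 times the library median in both libraries. The strongest was on chromosome 19 from 40479156 to 40479389, at 8.07 ± 2.58 (SD, n = 2), followed by chromosome 7 from 17000258 to 17000490 at 6.16 ± 1.48. Regions on chromosome 9 from 30179407 to 30179620, chromosome 1 from 39379439 to 39379641 and chromosome 14 from 36974692 to 36974915 had 5.13 ± 0.241, 5.11 ± 0.445 and 4.73 ± 0.331. The count of 114 became 61 at a −log10 q of at least 5, 669 with summits within 150 bp and 18 without high-background peaks. Lists of equal length gave 1158 regions of Ab1 alone and 592 of Ab2 alone. Without Ab1 replicate 2 or Ab2 replicate 1 the Ab1 count was 30500 or 19167, and without Ab1 replicate 1, Ab2 replicate 1 or Ab2 replicate 2 the Ab2 count was 267, 391 or 907.

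Shared regions lay mostly toward the ends of the chromosomes. Of the 15390 on chromosomes, 70.5% (69.8 to 71.2) fell in the outermost 20% at either end of a chromosome, where an even spread would put 40%. The outermost 10% at either end held 20.5% and 21.0%, and the sixth of 10 equal parts held 2.10%. Regions of Ab1 alone fell in these outer parts in 70.2% of cases and those of Ab2 alone in 58.0% (48.8 to 66.8). Chromosome 13 was the densest with 1162 shared regions or 25.3 per Mb, followed by chromosome 11 with 22.8, chromosome 17 with 21.5 and chromosome 8 with 20.7. Chromosome 14 was the sparsest with 575 regions or 11.7 per Mb, and all chromosomes together held 16.2 per Mb. Chromosome 4, the chromosome in the identifier of the studied gene, held 744 shared regions.

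**Figure D4:**
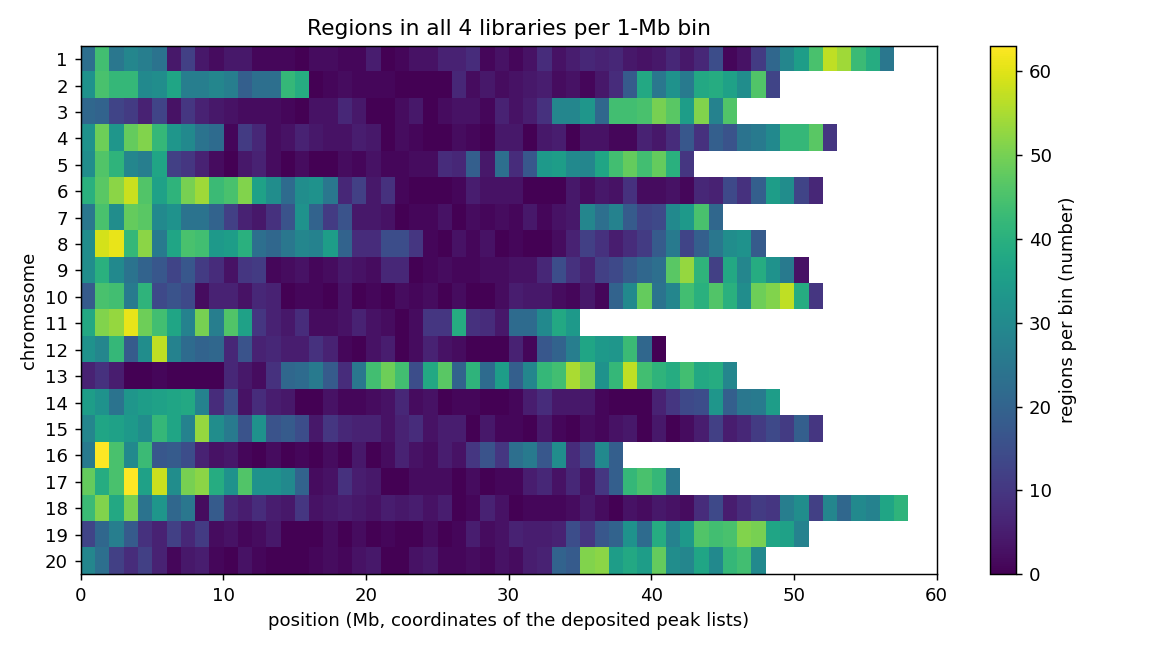
Shared regions per 1-Mb bin (colour) along each of the 20 chromosomes (rows), with the position in Mb on the horizontal axis and each chromosome drawn to its last peak. Most bins with many regions lie toward chromosome ends, up to 63 regions per bin on chromosomes 16 and 17, and chromosome 13 has its dense part on one side.

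The densest 1-Mb bins were chromosome 16 from 1 to 2 Mb and chromosome 17 from 3 to 4 Mb with 63 shared regions each, and chromosome 8 from 2 to 3 Mb and chromosome 11 from 3 to 4 Mb with 61 each. The median over 956 bins was 8 regions, and 93 bins held none. The measures of position along chromosomes, the 20% bound included, were chosen after the data were seen. Chromosome ends were taken as the last peak of any library, and mappability and gene density along the chromosomes were not analysed here.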

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

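The alternatives for regions of 1 antibody alone, the removal of peaks with high background, the shifts of 10 to 100 kb, those for the share of Ab2 regions found with Ab1 and the share in the outer parts of chromosomes with all its alternatives were chosen after seeing the data. Of 85 alternatives, 25 moved a result, 0 reversed it and 60 kept it. Only the ratio of peaks and the overlaps over chance could be counted as reversed, and these could not be counted as moved. Every other result could only be kept or moved, so the 0 says nothing about them. The 60 kept a count within 1.5 times, the ratio of peaks above 1, a tested result on its side of the threshold or an untested value within its spread. They include settings that could not change a result, which are named below. Among these 60, shifts of 10 to 100 kb lowered the overlap over chance of Ab1, Ab2 and shared regions from 17.6, 45.4 and 25.4 to 9.36, 23.7 and 13.1 times, and the excess in mean Jaccard index of same-number over crossed pairs went from 0.009 to 0.0277 at equal list length and 0.0059 with summits within 150 bp. Equal list length moved the Ab1 regions to 16042, Ab1 alone to 1158 and Ab2 alone to 592. The irreproducible discovery rate moved Ab1, Ab2 and shared regions to 11696, 2601 and 2567, and the 50% reciprocal overlap moved shared regions to 5774. The cause of these changes was not tested. Merging the passing regions of both antibodies joined some of the 2601, which left 2581 Ab2 regions as the base of the share found with Ab1. Ab2 alone became 61 at the stricter q, 669 with summits within 150 bp and 18 without high-background peaks. The share of Ab2 regions found with Ab1, 98.1%, went to 83.8% at equal list length, 88.6% with summits within 150 bp, 58.3% with 50% reciprocal overlap, 99.46% with the irreproducible discovery rate, 98.8% without high-background peaks, 99.1% without Ab1 replicate 2, and 94.0% and 87.6% without Ab2 replicates 1 and 2. Leaving out 1 library gave a ratio of 1.81 to 2.43, 42031 to 58568 Ab1, 19571 to 25883 Ab2 and 15501 to 22684 shared regions, 14877 to 30500 of Ab1 alone and 142 to 907 of Ab2 alone, since 1 list then stood for its antibody. With the replicate number as a block the ratio was 2.10 (exact sign-flip p = 0.5, the smallest 2 pairs allow), and no call changed. Using no further threshold and counting each summit changed nothing because of how the lists were made, and the block leaves the ratio the same by its arithmetic. These settings say nothing about stability. The alternatives set out beforehand for promoters, genes, motifs and gene lists were not run. Depth limits what can be said of weak regions, since median summits held 18 to 35 fragments.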

Other observations

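The tests of high background in regions of Ab2 alone and of greater depth in replicate 1 were chosen only after the result was seen, as were the measures of position along chromosomes, the spacing of regions and the resemblance of libraries of the same number as a pattern to weigh.

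Shared regions often had a close neighbour. Of them, 3063 (19.9%) had another shared summit within 2 kb, against 11.9% ± 0.337 (SD over 100 draws) and at most 12.9% when summits were placed at random within the same Mb. The median distance to the nearest shared summit was 7.83 kb, and the densest bins, 10% of the 1-Mb bins, held 30.0% of the shared regions.

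The Ab1 lists were longer than the Ab2 lists. Strong sites that Ab1 alone recovers were argued against, since 0% of the strongest 10% of Ab1 regions lacked a peak in both Ab2 libraries; weak sites of that kind stay open. Lower depth of the Ab2 libraries was argued against as the whole cause: Ab1 peaks thinned to the depth and fragment length of the Ab2 library of the same number still numbered 1.88 times its peaks for number 1 and 1.51 times for number 2, although the thinning started from peaks already called. Lower sensitivity of the Ab2 libraries stays open and may contribute. Regions of Ab1 alone had a median percentile of 36.5 over both Ab1 lists, under the bound of 40 set for it, but 41.6 in replicate 1 and 32.6 in replicate 2. Of the Ab2 regions, 98.1% held a peak in both Ab1 libraries. That share fell under the bound of 90% set for it at equal list length (83.8%), with summits within 150 bp (88.6%), with 50% reciprocal overlap (58.3%) and without Ab2 replicate 2 (87.6%). Whether a difference in sensitivity comes from the antibodies or from the immunoprecipitations was not tested.

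Libraries of the same number resembled each other across antibodies in some measures. The replicate 1 lists were 1.34 (Ab1) and 1.32 (Ab2) times as long as those of replicate 2. Greater depth in fragments was argued against, since replicate 1 had 0.576 and 0.918 times the recovered depth. How the reads of Ab1 replicate 2 were put together is not known, which limits the Ab1 value. Coverage also grows with fragment length, and the lowest background was 2.34 in Ab2 replicate 1 against 2.22 in Ab2 replicate 2. Greater coverage of replicate 1 therefore stays open for Ab2. Material or input shared within a number may contribute: at equal list length the lowest Jaccard index of a same-number pair exceeded the highest of a crossed pair by 0.0143, in a test first written for list length, which it does not measure, whereas on the full lists a crossed pair had the highest index (0.495 and 0.318 for crossed, 0.412 and 0.419 for same-number pairs). For fold enrichment over shared regions, the mean Spearman rho (across regions, which are not independent) was 0.688 for same-number and 0.529 for crossed pairs, an excess of 0.159, which shrank to 0.00458 when regions were ranked by recovered fragments alone. A candidate explanation for the likeness in fold is therefore the input that serves as background for both antibodies; no biological explanation was tested.

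Regions of Ab2 alone had very low fold enrichment. Sites that Ab2 alone recovers outside high background were argued against as the main source of the low fold. Only 18 of the 114 regions (15.8%, 10.2 to 23.6) lacked high background, under the bound set for this. Their median fold was 4.48, against 1.66 and 1.61 for all regions of Ab2 alone in replicates 1 and 2. Whether regions with high background hold such sites stays open. The 18 regions without high background had a median percentile of 29.2 when each region's percentiles in both Ab2 lists were averaged. Shared regions stood at 59.8 (67.8 in replicate 1 and 59.6 in replicate 2 taken singly), but a peak in all 4 libraries itself selects strong regions. A low rank cannot tell whether a site belongs to Ab2 alone, and the strongest of the 18 stood at percentiles 95.6 and 74.0. Places of very high coverage in the input may account for the low fold of most regions of Ab2 alone. In 96 of the 114 (84.2%) the background was at least 10 times the library median in both libraries, with a median fold of 1.60. Peaks with such a background numbered 148 and 119 in the Ab2 lists, 5 and 0 in the Ab1 lists and 0 in regions of all 4 libraries. These counts cover called peaks only. Libraries of the same number appeared to share their input, so input coverage alone does not explain why Ab1 held no peak there. Of the 96 regions, 10 lay on chromosome 12 from 39184017 to 39194633, 4 on chromosome 1 from 53482477 to 53488547 and 4 on chromosome 15 from 47403258 to 47406249, with the others elsewhere, and clustering was not tested.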
